A study of Astyanax mexicanus with 20 samples.

How the data were processed

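Skeletal muscle of Astyanax mexicanus was profiled by RNA sequencing in 20 libraries from the river-dwelling surface form and the blind cave form of this fish. In each form muscle was injected with phosphate-buffered saline (control) or cardiotoxin, a snake venom toxin that kills muscle fibres. Injured muscle was collected 1, 7 or 14 days post injury (dpi). Controls have no stated day, so time since injection is not matched. Controls and 1 dpi had 3 libraries per form and the later stages 2. Per the labels, polyadenylated RNA was made into stranded libraries (TruSeq Stranded mRNA) and read as single 75-base reads on a NextSeq. The submitters' processing notes name STAR 2.7.3a and RSEM 1.3.0; the genome build and the annotation release are not given in the sources used here, so no gene position is given. The labels' accounts differ: 1 text describes fish in constant darkness sampled around a 24-hour cycle. The sample labels, used for grouping, give saline, or cardiotoxin and days. The hour of collection was not used here. Nothing in the labels states that the libraries of a group came from separate fish, so the p-values measure the spread between these libraries, which may be technical. Over 62 pairs of libraries with the same replicate number in different groups the median correlation of their deviations from the group means was 0.0288, against -0.0179 over 112 pairs with different numbers. Surface controls and surface 1 dpi libraries deviated together by number (0.137, 0.108 and 0.235), although the labels give no source for a pairing.

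The deposited table holds gene values in TPM (transcripts per 1000000), made by the authors with RSEM, for 27420 Ensembl gene identifiers with gene names. Each library sums to 1000000 by construction, so total counts and the depth of each library are unknown, and no counting interval or detection floor was computed. Gene names are those of the deposited table; 13363 of the genes kept have a symbol, 3521 (20.85%) have none, and 1007 share a symbol with another identifier. Where several identifiers share a symbol, each was tested on its own.

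Genes with at least 1 TPM in at least 2 libraries were kept (16884 genes; 2876 were at 0 in every library). TPM values were divided by median-of-ratios factors computed over 9467 genes with at least 1 TPM in every library (factors 0.593 to 1.92), and log2(scaled TPM + 1) was analysed with limma 3.58.1 in R 4.3.3 (linear model with 1 mean per group over all 20 libraries, 12 residual degrees of freedom, moderated test with a mean-variance trend). For each of 13 contrasts, Benjamini-Hochberg adjusted p under 0.05 called a gene. The contrasts were each injured stage against the control of its form, cave against surface fish at each stage, and the difference of the injury response between forms at each stage (interaction). Group levels are means of scaled TPM with SD over libraries; log2 fold changes have the SE of the model. The smallest exact two-sided p that 3 libraries against 3 can give is 0.1, so single genes were tested only in the model across all genes.

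The 21 gene lists covered myogenic regulators and muscle stem cells, mature fast muscle contraction, slow muscle contraction, macrophages, neutrophils, lymphocytes, inflammatory cytokines and signalling, interferon response, complement and coagulation, extracellular matrix and fibroblasts, DNA replication and mitosis, glycolysis and glycogen, mitochondrial respiration, lipid storage and metabolism, ubiquitin ligases, autophagy and atrophy, heat shock and protein folding, circadian clock, erythrocytes, endothelium, Schwann cells and nerve, and skin and epithelium. They were tested with camera (limma, inter-gene correlation preset to 0.01), which compares a list with all other genes, with p-values adjusted over the 21 lists of a contrast. camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparison with other genes, were run too. Of 124 list calls with the preset correlation, 0 held with an estimated one and 31 were also called by fry. Counts of list members past the threshold, over all genes or adjusted over the list alone, were not compared with shares of all genes. Genes were named by rule: the 5 largest rises and 5 largest falls per contrast past the threshold with a symbol and no overlap between groups, up to 3 members with the smallest adjusted p of each called list and of the myogenic list, and the fixed genes pax7a, pax7b, myod1, myog, myf5, mymk, ckma, mpx, mpeg1, il1b, mmp9, col1a1a, mki67 and pcna. Some results for single genes are not reported here. Of the fixed genes, mki67 was not found by name and pax7a was below the filter. Calls at different stages of a form are not independent, because they share the control libraries.

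The groups, contrasts, lists, naming rule and main alternatives were fixed before the data were examined. Alternatives were a pseudocount of 0.1, no filter, a filter of mean TPM of at least 5, unscaled TPM, quantile normalization, the replicate number as a block, a fit of only the groups compared, an added 2-fold requirement, and leaving out each library in turn. Leaving out 2 cave libraries together was added after seeing the data. Leaving out a library at 7 or 14 dpi leaves 1 library in that group, which is then assumed to vary like the other groups. Without scaling, the median of all genes shifted against the controls by 0.57 (log2) at 1 dpi, 0.28 at 7 dpi and -0.23 at 14 dpi in surface fish, and by 0.40, 0.07 and -0.01 in cave fish; changes are therefore reported relative to the typical gene. The fit was tested on data simulated for each gene from its real mean and residual spread, with genes independent. Of 100 genes shifted 4-fold, 91 and 85 were recovered for surface 1 and 14 dpi against control. In the 1 and 14 dpi interactions 80 and 61 were recovered. At 2-fold, 54, 44, 20 and 9 of 100 were recovered, and the false calls per simulation numbered 5, 7, 2 and 0. In that test all 3 list tests called the shifted list and 0 of 20 unchanged lists. Recovery was not split by gene level, so it is unknown for low genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.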

Results

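Muscle transcripts were measured in surface and cave fish. Saline controls and 1 day post injury (dpi) with cardiotoxin had n = 3 per form, and 7 and 14 dpi n = 2. The comparisons asked how each form responded to injury and where the forms differed. Libraries held 11150 to 15146 genes at 1 TPM or more. pvalb4, a calcium-buffering parvalbumin of fast fibres, was the most abundant transcript in every library (3.77% to 15.3% of TPM). Correlations between replicate libraries ran from 0.942 to 0.981, and the first 3 principal components held 27.5%, 19.7% and 13.1% of the variance. Scaling factors differed with the groups: 0.963 to 1.92 in surface fish at 1 dpi, 0.685 to 0.900 in surface controls and 0.593 to 0.661 in surface fish at 14 dpi. Levels are scaled TPM as mean ± SD, and fold changes are log2 with the limma SE. Each gene named as rising or falling against its controls had every injured library beyond every control library. Chance gives that for 10% of genes with 3 libraries against 3 and 20% with 2 against 3. In each of the 124 list calls the mean, the median and the test had the same sign.

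In surface fish at 1 dpi mmp9 (ENSAMXG00000007722), which encodes a gelatinase that degrades matrix at wounds, went from 3.59 ± 1.65 to 62.6 ± 9.99 (n = 3 and 3), a log2 change of 3.84 (SE 0.53, adjusted p = 0.000423). fosl1b, an AP-1 transcription factor subunit, went from 0.141 ± 0.244 to 19.1 ± 2.12 (log2 change 4.16, SE 0.28, adjusted p = 1.32e-06). Of 44 macrophage genes 15 rose and 1 fell (17 and 1 adjusted over the list alone). Among them were irf8, a myeloid transcription factor, from 2.40 ± 1.43 to 13.1 ± 2.54, and the cathepsin gene ctsla, from 133 ± 63.9 to 452 ± 88.1. Of 21 neutrophil genes 9 rose and 1 fell (11 and 1 adjusted over the list alone). Of 51 cytokine and signalling genes 10 rose and 1 fell (14 and 1 adjusted over the list alone), with socs3b, a feedback inhibitor of cytokine receptors, at 2.53. The endoplasmic reticulum chaperone genes hspa5 and PDIA6 rose by 2.19 and 2.57. They were among 13 of 44 heat shock and folding genes that rose while 1 fell (18 and 1 adjusted over the list alone). Of 54 fast muscle genes 33 fell and 2 rose (38 and 2 adjusted over the list alone). cacna1sb, the voltage sensor of excitation-contraction coupling, changed by -1.42 (SE 0.22). Of 44 clock genes 7 fell and 0 rose (16 and 0 adjusted over the list alone), including rorca at -1.08. Of 36 endothelial genes 7 rose and 1 fell (10 and 2 adjusted over the list alone), including the receptor kinase gene tie1 at 0.86.

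limma called 2492 genes in this comparison, 1410 up and 1082 down. Without scaling the split was 5783 up and 190 down. Ranked against other genes, fast muscle (mean -1.02, camera adjusted p = 7.67e-12) and clock genes (-0.66, adjusted p = 4.96e-06) were lower. Neutrophils (1.19, adjusted p = 9.64e-06) and heat shock genes (0.62, adjusted p = 3.96e-05) were higher. These 4 lists had adjusted p = 0.295 with an estimated correlation. Macrophages (0.85, adjusted p = 7.64e-07), cytokines and signalling (0.51, adjusted p = 0.00148) and endothelium (0.35, adjusted p = 0.00531) were higher, each with adjusted p = 0.546 with an estimated correlation. For these 7 lists each of the 3 injured libraries lay beyond all 3 controls, and the call held whichever library was left out. The neutrophil peroxidase gene mpx (ENSAMXG00000018553) rose by 1.60 (SE 0.43, adjusted p = 0.0206). Its adjusted p was 0.0549, 0.0507 and 0.07 without surface control replicates 2 and 3 and surface 1 dpi replicate 1. The count of genes was 1608 without surface 1 dpi replicate 2.

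Other lists at this stage rested on single libraries. The extracellular matrix list was lower (mean -0.32 but 0.35 with unscaled TPM, adjusted p = 0.00148, and adjusted p = 0.734 with an estimated correlation). Of its 85 genes 8 rose and 19 fell (9 and 25 adjusted over the list alone), and its adjusted p was 0.102 without surface control replicate 1. Members moved apart: the proteoglycan gene vcana rose from 1.82 ± 0.887 to 7.90 ± 0.910 and the matricellular gene ccn4a by 1.84. The mitochondrial list was higher (0.26, adjusted p = 0.0116, and adjusted p = 0.787 with an estimated correlation), with 6 of 86 genes up and 0 down in both counts. Without surface control replicate 1 its adjusted p was 0.7. DNA replication genes were higher (0.33, adjusted p = 0.0132, and adjusted p = 0.787 with an estimated correlation), with 5 of 70 up and 0 down (3 and 0 adjusted over the list alone). Leaving out surface control replicates 2 and 3 and surface 1 dpi replicate 2 gave adjusted p = 0.116, 0.195 and 0.0802. Skin genes were higher (0.86, adjusted p = 0.00985, and adjusted p = 0.787 with an estimated correlation), with 3 of 33 up and 0 down in both counts. That adjusted p was 0.088 without surface 1 dpi replicate 2. Schwann cell genes were lower (-0.19 but 0.39 with unscaled TPM, adjusted p = 0.0206, and adjusted p = 0.546 with an estimated correlation), with 1 of 27 up and 3 down (1 and 4 adjusted over the list alone). Leaving out surface control replicates 2 and 3 gave adjusted p = 0.109 and 0.0598. Myogenic genes were not called (adjusted p = 0.95, mean 0.07, median -0.10, test above other genes). Glycolysis genes were not called either (-0.25, adjusted p = 0.315), but were with a replicate block within surface control and surface 1 dpi (adjusted p = 0.0262). Neither were lymphocytes (adjusted p = 0.296) or interferon response genes (adjusted p = 0.745, mean 0.03, median -0.27, test below other genes).

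At 7 dpi in surface fish the cardiac actin gene actc1a went from 1.22 ± 1.04 to 503 ± 20.6 (n = 3 and 2; log2 change 7.92, SE 1.16, adjusted p = 0.00249). tnni2b.1, a troponin I gene, went from 1.90 ± 2.60 to 291 ± 79.1, and ankrd1b, a stretch-responsive ankyrin repeat gene, from 0.319 ± 0.374 to 124 ± 50.9. mymk, which encodes the myoblast fusion protein myomaker, went from 0.0681 ± 0.118 to 4.07 ± 1.19 (2.23, SE 0.21, adjusted p = 6.7e-05). The myogenic differentiation factor myog rose by 3.24 (SE 0.75, adjusted p = 0.0265). Its adjusted p was 0.0548, 0.0658, 0.219 and 0.0664 without surface control replicates 2 and 3 and surface 7 dpi replicates 1 and 2. Of 35 myogenic genes 7 rose and 1 fell (9 and 2 adjusted over the list alone), while the list as a whole was not called (0.30, adjusted p = 0.152). Of 44 macrophage genes 15 rose (35 adjusted over the list alone) and 0 fell, among them irf8 by 1.85. The adjusted p of irf8 was 0.0046, and 0.0768 without surface 7 dpi replicate 1. Of 25 lymphocyte genes 7 rose and 0 fell (12 and 1 adjusted over the list alone). Among falling genes was arg2, a mitochondrial arginase, from 50.1 ± 14.2 to 9.57 ± 4.40.

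limma called 776 genes at this stage, 525 up and 251 down, against 677 up and 41 down without scaling. The count was 64 without surface 7 dpi replicate 1, and 433 and 440 without surface control replicates 1 and 3. It was 13 where only the compared groups were fitted, where actc1a and ankrd1b were still called and tnni2b.1 was not (adjusted p = 0.0708). Macrophages (mean 1.28, adjusted p = 8.95e-17) and lymphocytes (0.83, adjusted p = 3.67e-07) ranked above other genes. Endothelium (-0.33, adjusted p = 6.45e-05) and clock genes (-0.47, adjusted p = 0.000229) ranked below them. In these 4 lists 2 of 2 libraries lay beyond all controls, and each had adjusted p = 0.365 with an estimated correlation. Schwann cell genes were lower (-0.25, adjusted p = 0.00174, and adjusted p = 0.389 with an estimated correlation), although neither library lay below all controls. These 5 calls held whichever library was left out. The Schwann cell mean was -0.47 and -0.08 without surface control replicates 1 and 2, and the clock mean -0.25 without replicate 3. Lymphocytes were at 0.55 without surface 7 dpi replicate 1 and endothelium at -0.20 without replicate 2. Of 27 Schwann cell genes 0 rose and 6 fell (0 and 8 adjusted over the list alone), and of 36 endothelial genes 1 rose and 2 fell (1 and 5 adjusted over the list alone). Of 44 clock genes 0 passed in either count.

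Other calls in surface fish at 7 dpi were lost without single libraries. Neutrophils (0.52, adjusted p = 0.0196), interferon response (0.63, adjusted p = 0.00161) and glycolysis genes (-0.39, adjusted p = 0.0134) had adjusted p = 0.65 with an estimated correlation. DNA replication (0.43, adjusted p = 0.00174) and extracellular matrix genes (-0.12 but 0.20 with unscaled TPM, adjusted p = 0.0207) had adjusted p = 0.658 with an estimated correlation. Over all genes 1 of 21 neutrophil, 1 of 28 interferon, 1 of 59 glycolysis, 0 of 70 replication and 2 of 85 matrix genes rose. The falls numbered 0, 0, 2, 0 and 1. Adjusted over the list alone the rises were 2, 1, 1, 0 and 3 and the falls 1, 0, 2, 0 and 5. For neutrophils adjusted p was 0.446 without surface 7 dpi replicate 1 and 0.0515 without surface control replicate 2, and for interferon genes 0.0865 without surface control replicate 1. For glycolysis it was 0.0669 and 0.125 without surface 7 dpi replicate 1 and surface control replicate 2. For the matrix list it was 0.696 and 0.79 without surface 7 dpi replicate 2 and surface control replicate 1. For DNA replication it was 0.745, 0.05 and 0.0517 without surface 7 dpi replicate 1 and surface control replicates 2 and 3. Fast muscle genes were not called (adjusted p = 0.093), with a mean of 0.13, a median of -0.39 and a test direction below other genes.

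At 14 dpi the named leukocyte and myogenic genes of surface muscle were not called against controls (n = 2 and 3). mpx changed by 0.01 (SE 0.48, adjusted p = 1), mmp9 by 0.26 (SE 0.59, adjusted p = 0.943), MPEG1, the perforin-2 gene of macrophages, by 0.65 (SE 0.45, adjusted p = 0.699) and myog by 1.34 (SE 0.75, adjusted p = 0.61). limma called 0 genes, with 1593 genes at an unadjusted p under 0.05. The slow muscle list, drawn up mainly but not only from slow-fibre sarcomere genes, ranked below other genes (mean -0.81, adjusted p = 1.57e-05, and adjusted p = 0.772 with an estimated correlation). In it 2 of 2 libraries lay below all controls, 0 of 14 genes fell over all genes and 6 adjusted over the list alone. This call held whichever library was left out, with means of -0.39 and -1.24 without surface 14 dpi replicates 1 and 2. Macrophages were higher (0.49, adjusted p = 1.51e-05, and adjusted p = 0.772 with an estimated correlation), although 1 library lay above and 1 below all controls. Without surface 14 dpi replicate 2 the macrophage mean was -0.14 and adjusted p = 0.446. Skin genes were lower (-0.84, adjusted p = 0.0106, and adjusted p = 0.894 with an estimated correlation), with adjusted p = 0.324 without surface 14 dpi replicate 2. Myogenic genes were higher (0.14 but -0.12 with unscaled TPM, adjusted p = 0.0179, and adjusted p = 0.772 with an estimated correlation). Leaving out surface 14 dpi replicate 1 and surface control replicate 3 gave adjusted p = 0.249 and 0.161. The mitochondrial list was higher (0.29 but -0.05 with unscaled TPM, adjusted p = 6.31e-06, and adjusted p = 0.891 with an estimated correlation). Its adjusted p was 0.464 and 0.618 without surface 14 dpi replicate 1 and surface control replicate 1. The glycolysis list was higher (0.25 but -0.06 with unscaled TPM, adjusted p = 0.0351, and adjusted p = 0.894 with an estimated correlation), with adjusted p = 0.421 and 0.619 without surface 14 dpi replicate 1 and surface control replicate 3.

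The remaining calls in surface fish at 14 dpi were of lower lists. Heat shock (mean -0.25, adjusted p = 0.0169), clock (-0.35, adjusted p = 0.0112) and Schwann cell genes (-0.29, adjusted p = 0.0169) had adjusted p = 0.772 with an estimated correlation. Endothelium (-0.14, adjusted p = 0.0351) had adjusted p = 0.891 and extracellular matrix genes (-0.17, adjusted p = 0.0179) adjusted p = 0.894 with an estimated correlation. Without surface 14 dpi replicate 2 adjusted p was 0.241 for clock, 0.305 for Schwann cells, 0.417 for endothelium and 0.148 for matrix genes, and without replicate 1 it was 0.49 for heat shock. Without surface control replicate 1 it was 0.171 for heat shock, 0.114 for endothelium and 0.618 for matrix genes. Without control replicate 2 it was 0.0881 for heat shock, 0.0992 for endothelium and 0.0888 for Schwann cells, and without control replicate 3 it was 0.487 for clock and 0.124 for Schwann cells. In the lists called at this stage, 4 of 86 mitochondrial genes were higher and 1 of 85 matrix genes lower adjusted over the list alone, beside the 6 slow muscle genes. The count of genes was 54 and 25 without surface 14 dpi replicates 1 and 2, and 1, 4 and 28 without surface control replicates 1, 2 and 3. It was 3 without surface 1 dpi replicate 3 and 1 and 4 without cave 14 dpi replicates 1 and 2.

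In cave fish at 1 dpi mpx went from 0.241 ± 0.0750 to 13.3 ± 8.68 (n = 3 and 3; log2 change 3.23, SE 0.43, adjusted p = 7.32e-05), with cave 1 dpi libraries at 18.0, 18.5 and 3.25. MPEG1 went from 7.37 ± 2.30 to 58.2 ± 7.54 (2.85, SE 0.40, adjusted p = 0.000118), and mmp9 from 8.37 ± 1.53 to 108 ± 67.4. The heme oxygenase gene hmox1a went from 0.803 ± 0.382 to 31.4 ± 9.47, and the actin regulator of leukocytes coro1a from 30.0 ± 7.69 to 214 ± 20.5. Of 44 macrophage genes 32 rose and 0 fell (33 and 1 adjusted over the list alone), and of 21 neutrophil genes 17 rose and 1 fell in both counts. Of 51 cytokine and signalling genes 18 rose and 2 fell (19 and 2 adjusted over the list alone). The immunoproteasome genes psmb8a and psmb9a rose by 2.71 and 2.08, among 7 of 28 interferon response genes that rose and 0 that fell in both counts. Of 54 fast muscle genes 23 fell and 0 rose (25 and 0 adjusted over the list alone). ppp1r3ca, a glycogen-targeting subunit of protein phosphatase 1, fell from 134 ± 25.6 to 18.4 ± 7.15, while gapdhs and gpia of glycolysis rose by 2.33 and 1.80. Proliferation genes mcm6 and uhrf1 rose by 1.80 and 1.73, among 14 of 70 replication genes up and 1 down (12 and 1 adjusted over the list alone). Of 44 clock genes 16 fell and 1 rose (18 and 1 adjusted over the list alone). The core activator arntl1b fell from 27.6 ± 8.85 to 8.18 ± 2.80, and the repressor gene nfil3 rose by 1.88. Of 27 Schwann cell genes 9 fell and 1 rose (11 and 1 adjusted over the list alone), with erbb3a, the neuregulin receptor, at -1.18 and cnp, a myelin enzyme gene, at 2.49.

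limma called 4191 of 16884 genes, 2659 up and 1532 down. The split was 4307 up and 219 down without scaling and 2131 up and 2011 down after quantile normalization. Without 2 keratin-rich cave libraries, chosen post hoc, the count was 2616. Neutrophils (mean 2.04, adjusted p = 9.19e-11) were higher and clock genes (-0.63, adjusted p = 1.78e-06) lower, each with adjusted p = 0.17 with an estimated correlation. Fast muscle (-0.88, adjusted p = 1.41e-11) and Schwann cell genes (-0.66, adjusted p = 4.44e-05) were lower, each with adjusted p = 0.218 with an estimated correlation. Macrophages (1.56, adjusted p = 2.52e-13, and adjusted p = 0.255 with an estimated correlation) were higher. So were cytokines and signalling (0.73, adjusted p = 0.000634, and adjusted p = 0.375 with an estimated correlation) and DNA replication (0.62, adjusted p = 0.000617, and adjusted p = 0.616 with an estimated correlation). Mitochondrial (-0.38 but 0.13 with unscaled TPM, adjusted p = 3.17e-06), glycolysis (-0.46 but 0.02 with unscaled TPM, adjusted p = 0.00863) and extracellular matrix genes (-0.22 but 0.24 with unscaled TPM, adjusted p = 0.00367) were lower. These 3 had adjusted p = 0.569 with an estimated correlation. Ubiquitin ligase, autophagy and atrophy genes were lower (-0.32 but 0.14 with unscaled TPM, adjusted p = 0.00785, and adjusted p = 0.336 with an estimated correlation). Of 86 mitochondrial genes 8 rose and 9 fell (8 and 0 adjusted over the list alone), and of 59 glycolysis genes 7 rose and 11 fell (8 and 11). Of 85 matrix genes 11 rose and 16 fell (11 and 20 adjusted over the list alone), and of 57 ubiquitin ligase, autophagy and atrophy genes 2 rose and 9 fell (2 and 7). These 11 calls held whichever library was left out, and 3 of 3 libraries lay beyond all controls except for Schwann cells, where 2 of 3 did. The mitochondrial mean was -0.24 without cave 1 dpi replicate 3. Interferon response genes were higher (0.58, adjusted p = 0.0265, and adjusted p = 0.616 with an estimated correlation), with adjusted p = 0.0787 without cave 1 dpi replicate 3. Lymphocytes were higher (0.52, adjusted p = 0.0242, and adjusted p = 0.569 with an estimated correlation), with 6 of 25 up and 1 down (7 and 1 adjusted over the list alone). That adjusted p was 0.0691 and 0.0924 without cave control replicate 2 and cave 1 dpi replicate 3. Heat shock (0.38) and skin genes (0.91) were not called (adjusted p = 0.0817 for each).

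In cave fish at 7 dpi, of 35 myogenic genes 11 rose and 0 fell (12 and 1 adjusted over the list alone). The fusion gene mymk was at 5.84 ± 1.93 (n = 2) and listed at 0 in the 3 controls. The satellite cell factor myf5 went from 1.20 ± 0.252 to 6.89 ± 0.900 (log2 change 1.84, SE 0.28, adjusted p = 0.00158). met, the hepatocyte growth factor receptor of satellite cells, went from 1.34 ± 0.416 to 10.1 ± 0.00779 (2.27, SE 0.24, adjusted p = 0.000125). myog rose by 4.37 (adjusted p = 0.00344, and 0.0525 without cave 7 dpi replicate 2). pax7b, a satellite cell marker, rose by 1.04 (adjusted p = 0.028). Its adjusted p was 0.0801, 0.0757, 0.13 and 0.193 without cave control replicates 1 and 2 and cave 7 dpi replicates 1 and 2. Other genes that rose were tnni2b.1 from 1.79 ± 1.07 to 387 ± 101, pvalb2 from 173 ± 136 to 10069 ± 2203 and ankrd1b from 0.198 ± 0.248 to 179 ± 9.73. Of 44 macrophage genes 13 rose (24 adjusted over the list alone) and 0 fell. Of 21 neutrophil genes 8 rose and 0 fell in both counts, with the chemokine receptor cxcr1 from 0.304 ± 0.295 to 3.68 ± 0.529. Of 86 mitochondrial genes 5 rose and 3 fell (6 and 16 adjusted over the list alone). Of 59 glycolysis and glycogen genes 1 rose and 5 fell (2 and 12 adjusted over the list alone).

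limma called 1247 genes at this stage, 906 up and 341 down, against 491 up and 73 down without scaling. The count was 758, 749 and 612 without cave control replicates 1, 2 and 3, 223 and 156 without cave 7 dpi replicates 1 and 2, and 734 without the 2 keratin-rich libraries. The myogenic list (mean 0.57, adjusted p = 0.00105) and neutrophils (0.88, adjusted p = 3.12e-05) ranked above other genes. Clock (-0.51, adjusted p = 9.04e-06), endothelium (-0.31, adjusted p = 8.15e-05), lipid (-0.26, adjusted p = 0.0016) and ubiquitin ligase, autophagy and atrophy genes (-0.28, adjusted p = 0.00445) ranked below. These 6 lists had adjusted p = 0.288 with an estimated correlation. Macrophages were higher (1.11, adjusted p = 7.91e-08, and adjusted p = 0.343 with an estimated correlation). Mitochondrial genes were lower (-0.48, adjusted p = 2.05e-10, and adjusted p = 0.442 with an estimated correlation), and so were glycolysis genes (-0.70, adjusted p = 1.2e-05, and adjusted p = 0.306 with an estimated correlation). DNA replication genes were higher (0.55, adjusted p = 0.000232, and adjusted p = 0.713 with an estimated correlation), with 2 of 70 up over all genes, 0 over the list alone and 0 down. In these 10 lists 2 of 2 libraries lay beyond all controls, and the call held whichever library was left out. Of 36 endothelial genes 2 rose and 5 fell (3 and 10 adjusted over the list alone), and of 44 clock genes 1 rose and 3 fell (1 and 8). Of 46 lipid genes 0 rose and 2 fell in both counts. Of 57 ubiquitin ligase, autophagy and atrophy genes 2 rose and 0 fell in both counts although the list ranked lower. Lymphocytes were higher (0.50, adjusted p = 0.00794, and adjusted p = 0.596 with an estimated correlation), with 2 of 25 up and 0 down (2 and 1 adjusted over the list alone). Schwann cell genes were lower (-0.34, adjusted p = 0.0017, and adjusted p = 0.306 with an estimated correlation), with 1 of 27 up and 4 down (2 and 7 adjusted over the list alone). These 2 lists had adjusted p = 0.0608 and 0.101 without cave 7 dpi replicate 1.

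**Figure D1:**
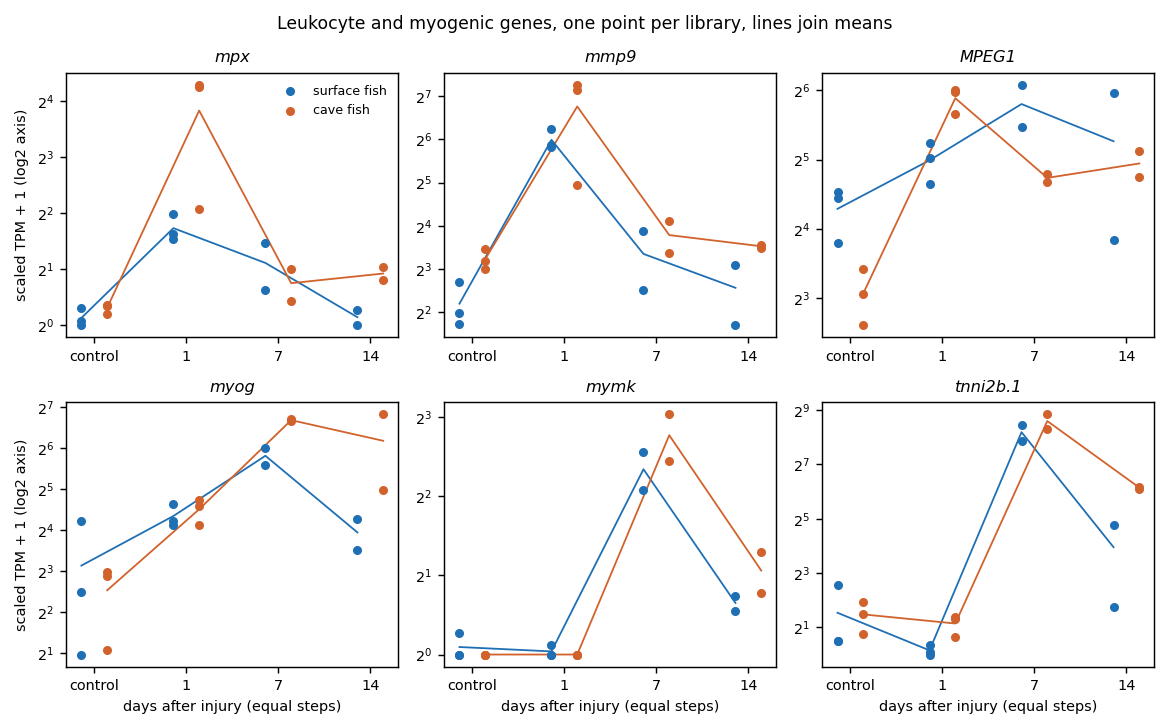
Scaled TPM + 1 (log2 axis) of mpx, mmp9, MPEG1, myog, mymk and tnni2b.1 by stage in surface fish (blue) and cave fish (orange); each point is 1 library, lines join group means, and stages are drawn at equal steps. tnni2b.1 averaged 291 scaled TPM in surface fish and 387 in cave fish at 7 dpi, against 1.90 and 1.79 in controls.

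In cave fish at 14 dpi pvalb2 was at 8049 ± 565 (n = 2) against 173 ± 136 in controls (n = 3), and tnni2b.1 at 69.9 ± 2.62 against 1.79 ± 1.07 (log2 change 4.75, SE 0.70, adjusted p = 0.00239). The myosin heavy chain gene myhb was at 201 ± 186 against 4.29 ± 4.16. Of 44 macrophage genes 20 rose (25 adjusted over the list alone) and 0 fell, including gpnmb, a glycoprotein of lipid-laden macrophages, from 0.577 ± 0.118 to 17.7 ± 2.56. Of 35 myogenic genes 11 rose and 0 fell (11 and 1 adjusted over the list alone), with met from 1.34 ± 0.416 to 6.08 ± 1.60. Of 70 DNA replication genes 25 rose and 2 fell (55 and 3 adjusted over the list alone). The cyclin gene ccnb1 was at 30.0 in replicate 1 and 3.07 in replicate 2, and its adjusted p of 0.0146 was 0.138 without replicate 1. ucp3, a mitochondrial uncoupling protein gene, went from 226 ± 101 to 17.6 ± 6.76, and ppp1r3ca from 134 ± 25.6 to 10.5 ± 4.69. SDHB, a subunit of succinate dehydrogenase, went from 110 ± 2.05 to 40.6 ± 1.19. Of 86 mitochondrial genes 4 rose and 10 fell (6 and 57 adjusted over the list alone). Of 27 Schwann cell genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), among them egr2b, the transcription factor of myelination, from 10.4 ± 0.989 to 2.63 ± 0.685 and mag at -1.75. Of 44 clock genes 10 fell and 1 rose (14 and 1 adjusted over the list alone), with the repressor gene cry1a from 47.1 ± 7.11 to 19.1 ± 2.49.

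limma called 1703 genes, 1050 up and 653 down, against 247 up and 271 down without scaling and 782 up and 751 down after quantile normalization. Where only the compared groups were fitted (5 libraries) limma called 0 genes, so the gene calls of this stage rest on the spread shared by all groups. The count was 768, 964 and 872 without cave control replicates 1, 2 and 3, 923 and 879 without cave 14 dpi replicates 1 and 2, and 911 without the 2 keratin-rich libraries. DNA replication (mean 1.21, adjusted p = 9.45e-14) and macrophages (1.17, adjusted p = 1.03e-08) ranked above other genes and mitochondrial respiration below (-0.65, adjusted p = 1.49e-15). These 3 had adjusted p = 0.379 with an estimated correlation. Clock (-0.58, adjusted p = 5.05e-07), Schwann cell (-0.78, adjusted p = 6.19e-07) and lipid genes (-0.39, adjusted p = 0.000147) were lower, each with adjusted p = 0.129 with an estimated correlation. Endothelium (-0.34, adjusted p = 6.86e-05) and ubiquitin ligase, autophagy and atrophy genes (-0.31, adjusted p = 0.00388) were lower, each with adjusted p = 0.332 with an estimated correlation. Neutrophils were higher (0.67, adjusted p = 0.00482, and adjusted p = 0.432 with an estimated correlation) and glycolysis genes lower (-0.44, adjusted p = 0.00216, and adjusted p = 0.446 with an estimated correlation). These 10 calls held whichever library was left out, with 2 of 2 libraries beyond all controls. Without cave 14 dpi replicates 1 and 2 the mean was 0.45 and 1.98 for DNA replication and -0.64 and -0.15 for lipid genes, and it was -0.22 for endothelium without replicate 2. Of 46 lipid genes 0 rose and 4 fell in both counts, and of 36 endothelial genes 1 rose and 7 fell (1 and 11 adjusted over the list alone). Of 57 ubiquitin ligase, autophagy and atrophy genes 2 rose and 5 fell (3 and 7 adjusted over the list alone). Neutrophils had 7 of 21 up and 0 down (8 and 0), and glycolysis 2 of 59 up and 3 down (2 and 2). The myogenic list was higher (0.36, adjusted p = 0.0431, and adjusted p = 0.426 with an estimated correlation). Its adjusted p was 0.0687, 0.0892, 0.0503, 0.0507 and 0.397 without cave control replicates 2 and 3, surface 1 dpi replicates 1 and 3 and cave 14 dpi replicate 2. Lymphocytes were higher (0.57, 2 of 25 up and 0 down, 1 and 0 adjusted over the list alone, adjusted p = 0.003, and adjusted p = 0.446 with an estimated correlation), with adjusted p = 0.418 without cave 14 dpi replicate 2. Matrix (-0.12, adjusted p = 0.015) and skin genes (-0.78, adjusted p = 0.00498) were lower, each with adjusted p = 0.676 with an estimated correlation. Of 85 matrix genes 4 rose and 7 fell and of 33 skin genes 1 rose and 2 fell, the same adjusted over the list alone. For the matrix list adjusted p was 0.249 and 0.065 without cave 14 dpi replicate 1 and cave control replicate 1. For skin the mean was 0.06 and adjusted p = 0.439 without cave control replicate 2. Fast muscle genes were not called (adjusted p = 0.794, mean 0.37, although the test direction was below other genes).

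**Figure D2:**
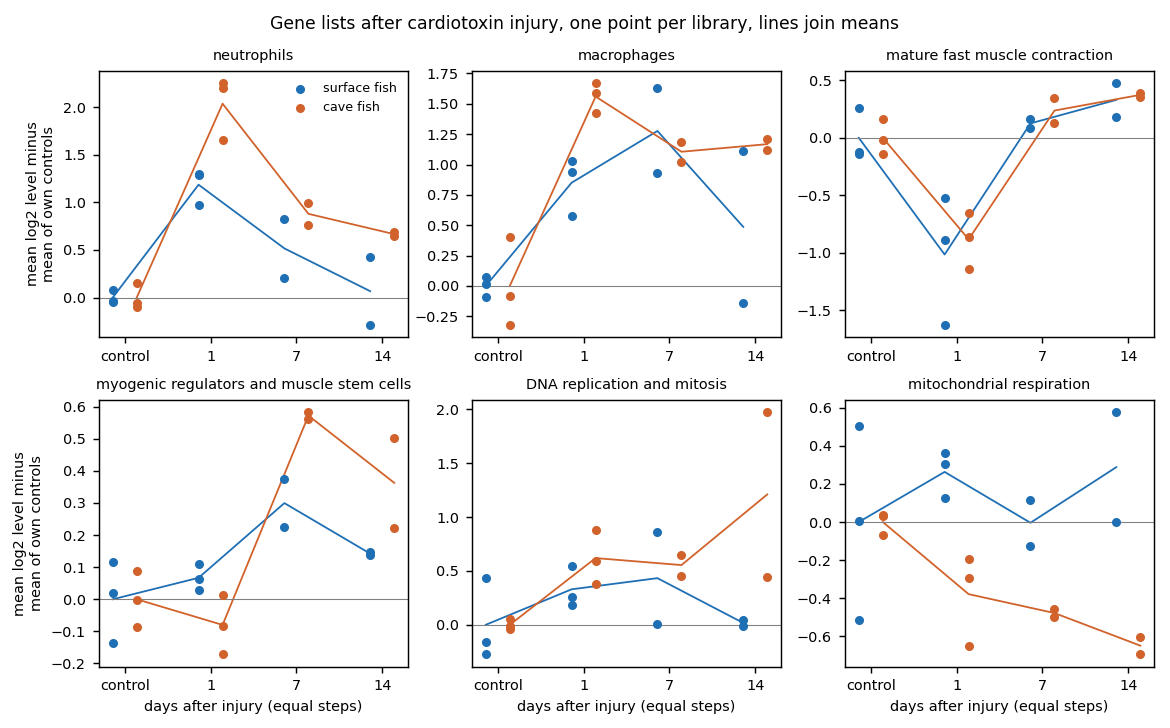
Mean log2 level of 6 gene lists minus the mean of the controls of the same form, by stage, in surface fish (blue) and cave fish (orange); each point is 1 library, lines join group means, and stages are drawn at equal steps. At 14 dpi the mitochondrial list averaged -0.65 in cave fish and 0.29 in surface fish, the latter -0.05 with unscaled TPM.

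Between the controls of the forms tac3b, a tachykinin precursor gene, was at 27.3 ± 11.9 in surface controls and 0.0875 ± 0.151 in cave controls (n = 3 and 3; log2 difference -4.61, SE 0.38, adjusted p = 9.71e-07). The tropomyosin gene TPM1 was at 299 ± 103 in surface and 4857 ± 1367 in cave controls (4.03, SE 0.37, adjusted p = 3.16e-06). pdca was listed at 0 in surface controls and at 15.2 ± 3.86 in cave controls. Reads of both forms share 1 table whose reference build is not given in the sources used here, so sequence differences from the reference are not separated from differences in level. Glycolysis and glycogen genes ranked higher in cave controls (mean 0.40, 3 of 3 libraries above all surface controls, adjusted p = 0.0293, and adjusted p = 0.955 with an estimated correlation). Of 59 genes 2 were higher and 0 lower in both counts, with pygmb, a glycogen phosphorylase, at 1.87 and gys1, glycogen synthase, at 0.98. The list had adjusted p = 0.238, 0.0515 and 0.0933 without surface control replicate 3 and cave control replicates 1 and 3. pygmb had 0.0694 and 0.0843 without surface control replicate 3 and cave control replicate 2. gys1 had 0.0838, 0.0905, 0.0559, 0.0827 and 0.0589 without surface control replicates 1 and 3 and cave control replicates 1, 2 and 3. Interferon response genes ranked lower (-0.46, 1 of 3 libraries below all surface controls, adjusted p = 0.0293, and adjusted p = 0.955 with an estimated correlation), with 0 of 28 genes past the threshold in both counts. That list had adjusted p = 0.456, 0.06, 0.0515 and 0.123 without surface control replicates 2 and 3 and cave control replicates 1 and 3. limma called 1475 genes, 773 higher and 702 lower in cave fish, against 689 and 259 without scaling, and 894 genes without cave control replicate 1. The 19 other lists were not called, among them complement and coagulation (mean -0.12, median 0.12, test above other genes, adjusted p = 0.63), which was called in no contrast.

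Between the forms at 1 dpi cxcr1 was at 3.19 ± 0.608 in cave and 0.375 ± 0.106 in surface fish (n = 3 and 3; log2 difference 1.60, SE 0.21, adjusted p = 0.000143). lect2l, a neutrophil chemotactic factor, was at 21.2 ± 11.7 and 3.59 ± 1.28, and csf1ra, the receptor for macrophage colony-stimulating factor, at 23.4 ± 4.03 and 11.0 ± 1.03. Of 44 macrophage genes 11 were higher and 0 lower (24 and 0 adjusted over the list alone), and of 21 neutrophil genes 10 were higher and 1 lower (12 and 1). Of 86 mitochondrial genes 35 were lower and 3 higher (62 and 3 adjusted over the list alone), with uqcrc2b of respiratory complex III at 104 ± 19.0 in cave and 255 ± 27.4 in surface fish. Of 14 slow muscle genes 3 were lower in both counts, including the slow troponin gene tnni1b at -1.68. mpx was higher by 1.82 (SE 0.43, adjusted p = 0.0128), with adjusted p = 0.0585 and 0.0688 without cave 1 dpi replicates 1 and 2.

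In this comparison limma called 1960 genes, 1190 higher and 770 lower in cave fish. The count was 1267, 1209 and 1217 without surface 1 dpi replicates 1, 2 and 3, 1031 and 1263 without cave 1 dpi replicates 2 and 3, and 1252 without the 2 keratin-rich libraries. Macrophages (mean 0.74, adjusted p = 2.65e-07) and neutrophils (0.94, adjusted p = 3.55e-05) were higher, and mitochondrial (-0.65, adjusted p = 5.42e-18) and slow muscle genes (-0.69, adjusted p = 0.004) lower. These 4 calls held in 3 of 3 libraries and whichever library was left out, each with adjusted p = 0.544 with an estimated correlation. Endothelium (-0.24, adjusted p = 0.004) and erythrocyte genes (-0.60, adjusted p = 0.0375) were lower, each with adjusted p = 0.544 with an estimated correlation. Of 36 endothelial genes 1 was higher and 3 lower in both counts, and of 12 erythrocyte genes 1 was higher and 0 lower (1 and 5 adjusted over the list alone). For endothelium adjusted p was 0.0636 without cave 1 dpi replicate 3. Erythrocytes had 1 of 3 libraries below all surface libraries. Their call was lost without cave 1 dpi replicates 1 and 3, surface 1 dpi replicates 1 and 2 and surface 7 dpi replicates 1 and 2 (adjusted p = 0.0532, 0.0636, 0.169, 0.0677, 0.0626 and 0.0517).

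At 7 dpi cxcr1 was higher in cave fish, at 3.68 ± 0.529 against 0.386 ± 0.172 (n = 2 and 2; log2 difference 1.76, SE 0.25, adjusted p = 0.000617). tac3b was lower by -4.89. met was higher by 1.35 (adjusted p = 0.00771), with adjusted p = 0.0907, 0.0687 and 0.0578 without surface 7 dpi replicate 2 and cave 7 dpi replicates 1 and 2. The myogenic list was higher in cave fish (mean 0.26, adjusted p = 0.00974), while interferon response (-0.74, adjusted p = 0.000335) and mitochondrial genes (-0.49, adjusted p = 7.89e-09) were lower. These 3 calls held in 2 of 2 libraries and whichever library was left out, each with adjusted p = 0.9 with an estimated correlation. Of 35 myogenic genes 2 were higher and 0 lower in both counts. Of 28 interferon genes 0 were higher and 1 lower (0 and 8 adjusted over the list alone), and of 86 mitochondrial genes 0 were higher and 1 lower (0 and 0). Lymphocytes (-0.43, adjusted p = 0.00514) and slow muscle genes (-0.56, adjusted p = 0.0379) were lower and neutrophils (0.45, adjusted p = 0.0259) and extracellular matrix genes (0.28, adjusted p = 0.00769) higher, each with adjusted p = 0.9 with an estimated correlation. Over all genes 0 lymphocyte, 0 slow muscle, 2 neutrophil and 5 matrix genes were higher and 1, 0, 0 and 2 lower, with 7 matrix genes higher and no other change adjusted over the list alone. Without surface 7 dpi replicate 1 lymphocytes had adjusted p = 0.513 and slow muscle 0.0774. Without replicate 2 neutrophils and matrix genes had adjusted p = 0.337 and slow muscle 0.0712. Leaving out cave 7 dpi replicate 1 gave 0.735 for slow muscle, replicate 2 gave 0.0899 for neutrophils, and cave 1 dpi replicate 3 gave 0.0549 for slow muscle. limma called 770 genes, 431 higher and 339 lower in cave fish. The count was 500 and 339 without surface 7 dpi replicates 1 and 2, 253 and 337 without cave 7 dpi replicates 1 and 2, and 215 where only the compared groups were fitted.

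At 14 dpi mitochondrial genes were lower in cave than in surface fish in 51 of 86 cases and higher in 3 (71 and 3 adjusted over the list alone). The list call (mean -0.95, 2 of 2 libraries, adjusted p = 2.7e-23, and adjusted p = 0.869 with an estimated correlation) held whichever library was left out. per3, a period gene of the clock, was lower in cave fish (n = 2 and 2; log2 difference -2.11, SE 0.34, adjusted p = 0.00122). pgpep1l, a pyroglutamyl peptidase-like gene, was at 0.523 ± 0.394 and 14.8 ± 0.902, and tac3b was listed at 0 in cave fish and at 55.1 ± 40.2 in surface fish. These 3 calls held whichever library was left out. uqcrc2b was lower by -1.52 (adjusted p = 0.00763) and cpt1b, which carries fatty acids into mitochondria, by -2.54 (adjusted p = 0.00876). met was higher by 1.40 (adjusted p = 0.00422) and the collagenase gene mmp13b by 3.55 (adjusted p = 0.00273). Without surface 14 dpi replicate 1 these 4 genes had adjusted p = 0.118, 0.136, 0.0653 and 0.0523. limma called 2053 genes, 1168 higher and 885 lower in cave fish, against 1265 and 188 without scaling. The count was 497 without surface 14 dpi replicate 1, 1181 without cave 14 dpi replicate 2 and 24 where only the compared groups were fitted. In that fit 0 of the genes named in this paragraph were called. DNA replication (0.98, adjusted p = 3.98e-07) and neutrophils (0.69, adjusted p = 0.0319) were higher with adjusted p = 0.869 with an estimated correlation, and macrophages (0.71, adjusted p = 0.00906) with adjusted p = 0.912 with an estimated correlation. Of 70 replication genes 3 were higher and 2 lower (2 and 2 adjusted over the list alone), of 21 neutrophil genes 4 and 0 (6 and 0), and of 44 macrophage genes 4 and 0 (3 and 0). DNA replication had adjusted p = 0.414 without cave 14 dpi replicate 1, and macrophages 0.961 without surface 14 dpi replicate 1. Neutrophils had 0.294 and 0.124 without surface 14 dpi replicate 1 and cave 14 dpi replicate 2. Schwann cell (-0.25 but 0.09 with unscaled TPM, adjusted p = 0.0287), lipid (-0.17 but 0.17 with unscaled TPM, adjusted p = 0.0319) and clock genes (-0.22 but 0.15 with unscaled TPM, adjusted p = 0.0361) were lower, each with adjusted p = 0.869 with an estimated correlation. Of their 27, 46 and 44 genes 2, 1 and 1 were higher and 6, 9 and 8 lower (3, 3 and 3 and 7, 13 and 8 adjusted over the list alone). Without surface 14 dpi replicate 1 they had adjusted p = 0.083, 0.101 and 0.101, and without cave 14 dpi replicate 2 they had 0.114, 0.443 and 0.205.

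The injury responses of the forms, which share no libraries, were then compared. Across all 16884 genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.724 and Spearman's rho = 0.669 at 1 dpi, 0.650 and 0.621 at 7 dpi, and 0.292 and 0.238 at 14 dpi. Leaving out single libraries moved Pearson's r between 0.680 and 0.734 (jackknife SE 0.0682) at 1 dpi and between 0.505 and 0.683 (SE 0.164) at 7 dpi. At 14 dpi it moved between 0.0411 and 0.420 (SE 0.301). At 1 dpi 1170 genes rose in both forms (222 if calls were independent), 598 fell in both (98.2) and 2 were called in opposite directions. At 7 dpi the numbers were 316 (28.2), 63 (5.07) and 1.

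**Figure D3:**
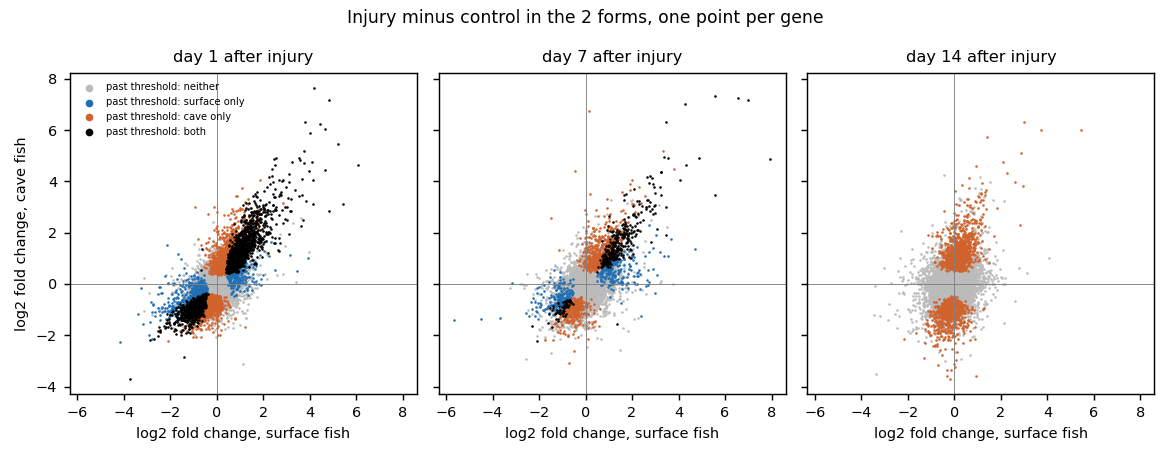
Log2 fold change of injured against control muscle in surface fish (x axis) and cave fish (y axis) at 1, 7 and 14 dpi; each point is 1 gene, coloured by whether it passed the threshold in neither form, 1 form or both. Pearson's r across genes was 0.724, 0.650 and 0.292.

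Single genes whose response differed between the forms at 1 dpi, tested as an interaction, included emb (ENSAMXG00000035855), an immunoglobulin-family partner of lactate transporters. It went from 0.338 ± 0.158 to 9.98 ± 3.27 in cave fish and from 0.565 ± 0.218 to 0.451 ± 0.126 in surface fish (n = 3 in each group; difference 3.10, SE 0.27, adjusted p = 0.00012). This call held in each leave-out and each alternative that kept the gene. pik3ap1, an adaptor that couples immune receptors to PI3 kinase, went from 1.92 ± 0.417 to 6.50 ± 0.279 in cave fish and from 7.87 ± 1.45 to 4.78 ± 0.672 in surface fish (1.98, SE 0.25, adjusted p = 0.00428). mpx (1.64, adjusted p = 0.402), MPEG1 (2.14, adjusted p = 0.219) and cxcr1 (1.39, adjusted p = 0.0894) were not called as differing in response. limma called 19 genes (16 with a higher and 3 with a lower log2 change in cave fish; 1636 at an unadjusted p under 0.05). Macrophages (mean 0.71, adjusted p = 1.58e-07, and adjusted p = 0.465 with an estimated correlation) and neutrophils (0.85, adjusted p = 1.58e-05, and adjusted p = 0.397 with an estimated correlation) rose more in cave fish. Mitochondrial (-0.64, adjusted p = 1.28e-20) and endothelial genes (-0.38, adjusted p = 4.39e-07) changed by -0.38 and -0.03 in cave and 0.26 and 0.35 in surface fish, each with adjusted p = 0.397 with an estimated correlation. These 4 list calls held whichever library was left out, and the mitochondrial mean was -0.39 without surface control replicate 1. Of their members 0 passed over all genes, and adjusted over the list alone 2 of 44 macrophage and 10 of 21 neutrophil genes were higher and 1 neutrophil and 5 of 36 endothelial genes lower. The count of 19 was 38 without cave 1 dpi replicate 3 and 7 without cave 1 dpi replicates 1 or 2. It was 11, 9 and 4 without surface control replicates 1, 2 and 3, 4, 9 and 7 without cave control replicates 1, 2 and 3, and 10, 11 and 9 without surface 1 dpi replicates 1, 2 and 3.

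At 7 dpi the interaction named 3 genes. SNORD15, a small nucleolar RNA, went from 0 to 1.57 in surface fish and from 1.99 to 0 in cave fish (adjusted p = 0.00132). gch2, a GTP cyclohydrolase of pteridine synthesis, went from 0.186 to 2.54 in surface fish and was listed at 0 in cave fish at both stages (adjusted p = 0.0086). myl4, an embryonic myosin light chain, was listed at 0 in both controls and at 1.03 ± 0.582 in surface and 5.34 ± 0.0712 in cave fish (adjusted p = 0.0086). gch2 had adjusted p = 0.0699 and 0.0889 without cave 7 dpi replicates 1 and 2, and myl4 had 0.0514, 0.0838 and 0.118 without surface 7 dpi replicate 1 and cave 7 dpi replicates 1 and 2. limma called 8 genes (5 higher and 3 lower; 808 at an unadjusted p under 0.05). The count was 16 and 4 without surface 7 dpi replicates 2 and 1, 3 without cave 7 dpi replicates 1 or 2, and 13 without cave 14 dpi replicates 1 or 2. The myogenic list rose more in cave fish (mean 0.27, adjusted p = 0.00308, and adjusted p = 0.78 with an estimated correlation) and the mitochondrial list changed by -0.48 in cave and 0.00 in surface fish (-0.47, adjusted p = 4.28e-11, and adjusted p = 0.93 with an estimated correlation). Both calls held whichever library was left out, with 0 member genes past the threshold in either count. The mitochondrial mean was -0.22 and -0.72 without surface control replicates 1 and 2.

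At 14 dpi ppp1r3ca went from 134 ± 25.6 to 10.5 ± 4.69 in cave fish and from 21.4 ± 2.13 to 42.3 ± 16.1 in surface fish (n = 3 and 2 in each form; difference -4.51, SE 0.70, adjusted p = 0.0353). CMC1, a cytochrome c oxidase assembly factor, changed by -0.96 in cave and 1.24 in surface fish (-2.21, SE 0.32, adjusted p = 0.0259). pgap2, of GPI anchor remodelling, went from 1.81 to 4.09 and from 2.09 to 0.712 (1.70, adjusted p = 0.0353). ENSAMXG00000035259 (2.30, adjusted p = 0.0259) and ENSAMXG00000040589 (-2.20, adjusted p = 0.0259), which have no symbol, were chosen after their values were seen. CMC1 was lost without surface control replicate 1 (adjusted p = 0.0542), cave control replicates 1 and 3 (0.0677 and 0.058), surface 1 dpi replicate 2 (0.0542), cave 1 dpi replicate 2 (0.0559) and surface 14 dpi replicate 1 (0.0541). ppp1r3ca was lost without surface control replicates 1 and 2, any cave control, surface 1 dpi replicate 2, cave 1 dpi replicate 2, any 7 dpi library or surface 14 dpi replicate 1 (adjusted p from 0.052 to 0.119). pgap2 was lost without surface control replicate 1, any cave control, surface 1 dpi replicates 1 and 2, cave 1 dpi replicate 2, either surface 7 dpi library, surface 14 dpi replicate 1 or cave 14 dpi replicate 1 (adjusted p from 0.0542 to 0.102). limma called 5 genes (2 higher and 3 lower; 2648 at an unadjusted p under 0.05). The count was 0 without cave control replicates 1 or 3, surface 1 dpi replicate 2 or cave 1 dpi replicate 2. It was 318 and 11 without surface 14 dpi replicates 2 and 1, 26 and 277 without cave 14 dpi replicates 1 and 2, 2, 11 and 186 without surface control replicates 1, 2 and 3, and 8 without cave 1 dpi replicate 3. Slow muscle (mean 1.20, adjusted p = 0.00392) and DNA replication genes (1.19, adjusted p = 1.21e-11) changed by 0.38 and 1.21 in cave and -0.81 and 0.02 in surface fish, and glycolysis genes (-0.69, adjusted p = 5.19e-05) by -0.44 and 0.25, each with adjusted p = 0.466 with an estimated correlation. Mitochondrial (-0.94, adjusted p = 9.87e-26), Schwann cell (-0.48, adjusted p = 0.000932) and ubiquitin ligase, autophagy and atrophy genes (-0.30, adjusted p = 0.00657) changed by -0.65, -0.78 and -0.31 in cave and 0.29, -0.29 and -0.01 in surface fish, each with adjusted p = 0.407 with an estimated correlation. These 6 list calls held whichever library was left out. Without cave 14 dpi replicates 1 and 2 the DNA replication mean was 0.44 and 1.96. Slow muscle was at 0.77 without surface 14 dpi replicate 1, ubiquitin ligase genes at -0.20 without replicate 2, and Schwann cells at -0.27 without surface control replicate 1. Of their members 0 passed over all genes. Adjusted over the list alone 28 of 86 mitochondrial, 3 of 27 Schwann cell and 1 of 57 ubiquitin ligase, autophagy and atrophy genes were lower, and 0 genes of the other 3 lists passed.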

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

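The tests of single libraries, a larger response, the hour of sampling, fibre transcripts and carried-in skin were chosen after the results were seen. The bounds for scaling, larger response and fibre transcripts were changed after their values were seen. The next 3 paragraphs were set apart because the injury response differed between the forms. 0 list calls of the interactions were shared by fry.

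At 1 dpi the count was 19 genes. Named genes that rose more in cave fish were emb (3.10), vav3a (2.18, adjusted p = 0.0253), c6ast1 (ENSAMXG00000029889), an astacin protease (2.01, adjusted p = 0.0244), pik3ap1 (1.98) and f5, coagulation factor V (1.76, adjusted p = 0.0331). peli1a, a ubiquitin ligase of Toll-like receptor signalling (-1.97, adjusted p = 0.0315), and SNORD15 (-1.90, adjusted p = 0.0235) changed by -1.79 and -1.58 in cave and 0.18 and 0.33 in surface fish. Each of vav3a, c6ast1, f5, peli1a and SNORD15 was lost without 7 to 11 single libraries, cave control replicate 1 and cave 1 dpi replicate 1 among them each time (adjusted p from 0.0503 to 0.115). Lists were macrophages (0.71), neutrophils (0.85), mitochondrial respiration (-0.64, and -0.39 without surface control replicate 1), endothelium (-0.38) and 7 calls that hung on single libraries. Schwann cells (-0.47, adjusted p = 0.00431), myogenic (-0.15, adjusted p = 0.0182) and lipid genes (-0.23, adjusted p = 0.0246) had adjusted p = 0.397 with an estimated correlation. Interferon (0.55, adjusted p = 0.00115) and heat shock genes (-0.24, adjusted p = 0.0467) had adjusted p = 0.593 with an estimated correlation. Glycolysis (-0.21, adjusted p = 0.0246) had adjusted p = 0.655 and ubiquitin ligase, autophagy and atrophy genes (-0.19, adjusted p = 0.0453) adjusted p = 0.467 with an estimated correlation. Without cave 1 dpi replicate 3, adjusted p was 0.0785 for Schwann cells and lipid, 0.128 for myogenic genes and 0.156 for glycolysis, heat shock and ubiquitin ligase genes. The interferon call had adjusted p = 0.196 without surface control replicate 2, and heat shock was also lost without surface control replicate 3, cave control replicates 1 and 2, surface 1 dpi replicates 2 and 3 or any surface 7 or 14 dpi library (adjusted p from 0.0501 to 0.508). Glycolysis had 0.362 and 0.686 without surface control replicate 3 and surface 1 dpi replicate 1, myogenic genes 0.0769 and 0.0606 without surface control replicate 3 and cave control replicate 1, and lipid 0.0816 and 0.0565 without surface control replicate 1 and surface 1 dpi replicate 1. Ubiquitin ligase genes had 0.113, 0.196, 0.103, 0.0507 and 0.284 without surface control replicates 1 and 2, cave control replicates 1 and 3 and surface 1 dpi replicate 3.

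At 7 dpi the count was 8, with gch2 (-1.58), SNORD15 (-2.94) and myl4 (1.67). Lists were myogenic (0.27) and mitochondrial genes (-0.47, and -0.22 and -0.72 without surface control replicates 1 and 2) and 6 that hung on single libraries. Macrophages (-0.17), extracellular matrix (0.23 but -0.03 with unscaled TPM) and glycolysis genes (-0.31) had adjusted p = 0.012, and adjusted p = 0.936 with an estimated correlation. Neutrophils (0.36, adjusted p = 0.012), lymphocytes (-0.33, adjusted p = 0.0105) and lipid genes (-0.17, adjusted p = 0.0371) had adjusted p = 0.93 with an estimated correlation. Without surface 7 dpi replicate 1 adjusted p was 0.968 for macrophages and 0.921 for lymphocytes. Without replicate 2 it was 0.485 for neutrophils, 0.645 for matrix, 0.0759 for glycolysis and 0.349 for lipid genes. Without cave 7 dpi replicate 1 it was 0.0676 for glycolysis and lipid, and without replicate 2 it was 0.134 for macrophages and 0.064 for neutrophils, lymphocytes, matrix and lipid genes. Without surface control replicate 1 it was 0.0508 for macrophages, 0.707 for matrix and 0.232 for lipid genes, and without replicate 3 it was 0.281 for glycolysis. Without cave control replicate 1 it was 0.55 for macrophages, without replicate 2 it was 0.0539 for lipid, and without replicate 3 it was 0.05 for neutrophils, matrix and lipid genes.

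At 14 dpi the count was 5, with CMC1 (-2.21), ppp1r3ca (-4.51) and pgap2 (1.70). Lists were slow muscle (1.20, and 0.77 without surface 14 dpi replicate 1), DNA replication (1.19, and 0.44 and 1.96 without cave 14 dpi replicates 1 and 2), glycolysis (-0.69), mitochondrial (-0.94), Schwann cell (-0.48, and -0.27 without surface control replicate 1) and ubiquitin ligase, autophagy and atrophy genes (-0.30, and -0.20 without surface 14 dpi replicate 2), and 5 that hung on single libraries. Lipid (-0.33, adjusted p = 0.00115) and clock genes (-0.23, adjusted p = 0.00354) had adjusted p = 0.407 with an estimated correlation. Macrophages (0.68, adjusted p = 0.00591) had adjusted p = 0.793, neutrophils (0.60, adjusted p = 0.0205) adjusted p = 0.589 and endothelium (-0.20, adjusted p = 0.0116) adjusted p = 0.552 with an estimated correlation. Without surface 14 dpi replicate 1 adjusted p was 0.911 for macrophages, 0.394 for neutrophils and 0.752 for endothelium. Without cave 14 dpi replicate 2 it was 0.0757 for neutrophils, 0.0838 for lipid and 0.188 for endothelium. Leaving out surface control replicates 2 and 3 gave 0.0812 for clock and 0.0633 for endothelium. Leaving out cave control replicate 2 gave 0.0507 for neutrophils, and replicate 3 gave 0.0586 for macrophages and 0.0574 for neutrophils.

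Splits of the libraries asked how many genes other groupings would call. The real grouping was the only 1 of 10 splits with as many genes for surface 1 dpi against control (2492, highest other 10), cave 1 dpi against control (4191, highest other 2), the controls of the forms (1475, highest other 3) and the forms at 1 dpi (1960, highest other 1), but 10 splits are too few for a share under 0.05. For surface 1 dpi 3 other splits part as many same-numbered pairs (highest 2 genes). For the 1 dpi interaction 13 of 100 drawn assignments of form (200 possible), the real one included, called 19 genes or more, so chance was not excluded. The 12 others each exchanged unequal numbers of controls and injured libraries, among them the highest (637 genes, 2 controls and 0 injured exchanged), which carries the difference between the forms into the interaction. The drawn assignments therefore decide little about that count.

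Genes raised at 7 dpi in 1 form were followed in the other form, so the gene sets differ between the forms; at 14 dpi library medians were 0.801 and 0.940 in cave fish (525 genes; 1.07 and 1.06 at 7 dpi) and -0.0547 and 0.403 in surface fish (906 genes; 0.969 and 0.624 at 7 dpi). Scaling cannot be told apart: the gap between the lowest cave and the highest surface library, 0.398, was 0.180 with unscaled TPM and 0.311 after quantile normalization, and the first bound, a gap above 0, ignored that libraries of a form lay up to 0.458, 0.621 and 0.402 from each other in these settings. For the same reason a single library cannot be told apart, of 14 dpi (0.914 without surface 14 dpi replicate 2) or of another stage (smallest gap 0.343, without cave 7 dpi replicate 2). Neither can a larger cave response at every stage be told apart: the 316 genes raised in both forms had a mean rise of 1.82 in cave fish at 7 dpi (libraries 1.79 and 1.84) against 1.83 and 1.38 in surface libraries. A slower repair in cave fish stays open and was not tested.

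Clock genes were lower after injury in both forms, and another hour of sampling was taken to move the activator arm (arntl, clock and npas2 genes) against the output arm (nr1d and PAR bZIP genes). In cave fish at 1 dpi the arms fell together (-0.75 and -0.68, each below all controls in 3 of 3 libraries). In surface fish they were at -0.54 (2 of 3 libraries) and -1.07 (3 of 3). The hour cannot be told apart in either form, as how the arms move with it was assumed, not measured. Fewer fibre transcripts cannot be told apart in cave fish. At 14 dpi, with clock genes at -0.58, fast muscle genes had a median of 0.0575 (mean 0.37, SD over 54 genes 1.46). Their rank below other genes was not called, and 2 of 2 libraries lay above all controls.

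Skin and epithelium genes stood out in cave control replicate 2 and cave 1 dpi replicate 3. There 26 and 29 of 33 genes were over 2-fold above the other 2 libraries of the group (means 2.50 and 3.17), at percentile 100 of 10000 matched random lists (highest 0.581 and 0.63). Skin carried into the sample cannot be told apart, as the libraries were picked for these genes. Skin as the source of the leukocyte calls was excluded, since without both libraries macrophages were at 1.51 (adjusted p = 1.01e-11) and neutrophils at 2.19 (adjusted p = 3.04e-12).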

How the results depend on the processing

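Leaving out the 2 keratin-rich cave libraries and the replicate block within surface control and 1 dpi were chosen after the data were seen. The other tests here were planned. Of 351 gene calls and 124 list calls, 330 and 119 kept their direction and call with a pseudocount of 0.1, 330 and 111 without a filter, 282 and 101 without scaling, 339 and 108 after quantile normalization, 332 and 119 with a replicate block, and 185 and 117 where only the compared groups were fitted. With mean TPM of at least 5, 250 of 250 genes and 78 of 118 lists did so, and without the keratin-rich libraries 313 and 112. Single leave-outs kept 298 to 349 genes and 110 to 124 lists. The list calls rest on the preset correlation (0 kept with an estimated one) and the 14 dpi results on 2 libraries per form.

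A pseudocount of 0.1 gave 12 genes for surface 14 dpi against control, 7 and 2 for the 1 and 7 dpi interactions, and a correlation between the forms of 0.653 at 1 dpi. Without a filter surface 14 dpi had 15 genes and the interactions 32, 29 and 19. With mean TPM of at least 5 the counts were 4 for surface 14 dpi, 2683 and 1128 for cave 1 and 14 dpi, 762, 1109, 317 and 1276 for cave against surface fish as controls and at 1, 7 and 14 dpi, and 1, 1 and 12 for the interactions. Without scaling they were 5973 for surface 1 dpi, 564 and 518 for cave 7 and 14 dpi, 948 and 500 between the forms as controls and at 7 dpi, and 2 for the 14 dpi interaction, as after quantile normalization (2). A replicate block gave 12 for the 1 dpi interaction. Within surface control and surface 1 dpi a replicate block gave 2601 genes, kept 51 of 51 gene and 12 of 12 list calls and added glycolysis. Where only the compared groups were fitted the counts were 1098 and 13 for surface 1 and 7 dpi, 0 for cave 14 dpi, 592, 215 and 24 between the forms as controls and at 7 and 14 dpi, and 30, 14 and 2 for the interactions. Requiring a 2-fold change, which by construction can only remove genes, left 1201 for surface 1 dpi, 1917, 780 and 1010 for cave 1, 7 and 14 dpi, and 838 and 959 between the forms as controls and at 1 dpi. Without the keratin-rich libraries cave 1, 7 and 14 dpi had 2616, 734 and 911 and the forms at 1 dpi 1252. The cause of these shifts was not tested.

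Unscaled TPM turned the sign of list means, and the side that camera took in that setting was not recorded. Extracellular matrix genes were at 0.35 and 0.20 in surface fish at 1 and 7 dpi, 0.24 in cave fish at 1 dpi and -0.0266 in the 7 dpi interaction. Schwann cell genes were at 0.39 in surface fish at 1 dpi and 0.0907 in cave against surface fish at 14 dpi, where lipid was at 0.17 and clock at 0.15. In surface fish at 14 dpi glycolysis was at -0.0647 and mitochondrial respiration at -0.0492. In cave fish at 1 dpi glycolysis was at 0.0222, mitochondrial respiration at 0.13 and ubiquitin ligase, autophagy and atrophy genes at 0.14. Quantile normalization turned ckma, muscle creatine kinase, in surface fish at 1 dpi from -0.90 to 0.73 (limma adjusted p from 0.0486 to 0.0434, and from 0.0146 to 0.597 over all alternatives).

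Leaving out single libraries moved the counts from 1608 to 2662 for surface 1 dpi, 64 to 1062 for surface 7 dpi, 0 to 54 for surface 14 dpi, 2852 to 4326 for cave 1 dpi, 156 to 1523 for cave 7 dpi and 768 to 1948 for cave 14 dpi. Between the forms they ran from 894 to 1548 as controls, 1031 to 2166 at 1 dpi, 253 to 879 at 7 dpi and 497 to 2397 at 14 dpi. The interactions ran from 4 to 38, 3 to 16 and 0 to 318, and the correlations between the forms from 0.680 to 0.734, 0.505 to 0.683 and 0.0411 to 0.420.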

Other observations

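The 2 cave libraries of 14 dpi differed in proliferation transcripts. pcna, the sliding clamp of DNA replication, was at 36.8 in replicate 1 and 11.3 in replicate 2. nr1d1, a repressor of the clock, was at 94.6, 8.62 and 147 in the 3 surface controls. These differences within a group were picked after the values were seen and were not tested.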
